A study of Mus musculus with 32 samples.

How the data were processed

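The data were 43 lists of ATAC-seq peaks from mouse intestinal epithelium and cultures, 1 for each of 32 libraries and 1 for each of 11 groups, plus a merged list of regions. Per the labels' protocols, nuclei were isolated and tagmented with Illumina Nextera reagents. Per the submitters' processing notes, BWA and SAMtools were used and the genome build was mm10; versions and the peak caller are not given in the sources used here, nor whether read ends were shifted for the transposase. The lists as deposited have the 10 columns of the narrowPeak format. The deposited score in column 5 is 10 times the value of column 9. The fold enrichment that the authors deposited in column 7 is a ratio, and columns 8 and 9 hold the authors' −log10 p and −log10 q values, with no q above 0.05. Peak scores, folds and q values are the authors' own and were used only to rank peaks within a list. Peaks were called per library and again per group; the per-group lists entered no comparison. The deposited merged list of 288151 regions is identical to a merge of all 43 lists.

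Groups came from the sample labels. The spelling Igr5 in some titles was read as Lgr5, spheroid libraries are numbered 2 and 3, and the stage of 1 Lgr5-GFP group is not labelled and was not inferred. The titles of the spheroid and enteroid libraries give no stage of origin either, and none was inferred. The lists carry no read counts, so sequencing depth is unknown and the length of a list, 11934 to 123763 peaks, stands in for it. Shorter lists limit which regions can be called. In the main gene test a difference in presence was therefore measured only beyond each library's own call rates.

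Regions were those of the merged list on chromosomes 1 to 19 and X, 286902 in all, and a region counted as called in a library when at least 1 bp overlapped a peak of its own list (bedtools 2.31.1). Regions were assigned with a table of GRCm38.p6 genes, the assembly behind mm10, that gives no strand. The planned nearest transcription start was therefore replaced by the nearest protein-coding gene span within 50 kb, taking the shortest span where several overlapped, and the planned promoter class by a distance of 1 kb to either gene end. Of the regions 226898 (79.1%) had a gene within 50 kb, 148677 of them inside a gene span, and 20043 of 21631 genes had a region. Exons, introns and untranslated parts were not told apart.

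For each comparison only the libraries of its groups were used. Regions were put in strata by the number of these libraries that called them. The expected call of a region in a library was that library's call rate in the stratum, and the residual was the call minus this rate. A group difference shared by many regions of a stratum also enters this rate, so the residual removes more than list length. A region was variable when some but not all libraries called it. The value of a gene in a library, the call excess, was the mean residual over its variable regions, at least 3, in percentage points. A difference between groups can exceed 100 points because the expected calls of both groups enter it, and a positive difference can go with equal or fewer calls where one list is short. Excess is easier to detect in the group with the shorter lists.

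Gene values were compared with limma 3.58.1 in R 4.3.3 (empirical Bayes moderation with a trend on the log2 number of variable regions, two-sided, Benjamini-Hochberg adjustment at 0.05). A slope on embryonic day was fitted over the EpCAM libraries. In all, 37 lists of cell type markers, pathway genes and controls were fixed beforehand, of which 695 of 700 symbols matched, and each was tested with limma's camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists of a comparison. Of 21 list calls over 280 tests, 6 held with an estimated correlation, all of them in the slope on embryonic day. Peak numbers were compared with exact permutation tests over the 7 comparisons, and library similarity by the Jaccard index and the residual correlation with 100000 permutations of group labels (Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3; figures with Matplotlib 3.10.9).

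Named genes followed a rule. In each direction they were the 8 with the largest difference among genes past the threshold with at least 6 variable regions and separated libraries, then up to 10 listed genes past the threshold, and Bmi1, Lgr5 and Epcam in every case. Where fewer than 3 passed in a direction, the 3 with the smallest p were named. Some listed genes that the rule names are not reported here. Other listed genes were chosen as examples of their list after their values were seen. Groups, comparisons, tests, gene lists, this rule and the alternatives were fixed before the data were examined, except where a test is said to have been chosen later. The steps between neighbouring days were added afterwards.

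Alternatives were lists trimmed to equal length by score, the top 50% of each list, a call only where 50% of a region was covered, regions merged from the library lists and called in at least 2 libraries, a 20 kb limit, strata that also separate regions near gene ends, log2 of covered length per gene, scaled to each library's covered length, plus a pseudocount of 1, a block on replicate number, and each library left out in turn.

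The gene test was tested on simulated calls drawn from a logistic model of the real libraries. With a small part of the genes shifted at an odds ratio of 16, the E17.5 against E12.5 design recovered 63% of genes shifted up and 38.8% of those shifted down over 9285 genes. The E17.5 Bmi1-GFP design recovered 18.4% up and 0 down (7566 genes), the spheroid design 22.2% up and 0 down (6854 genes), and the comparison with the unlabelled stage 29.3% up and 0 down (8663 genes). The adult Bmi1-GFP against Lgr5-GFP design (7993 genes) and the irradiation design (4038 genes) recovered 0 in both directions, and the adult against E17.5 Bmi1-GFP design 5.7% up and 0 down (5343 genes), so a count of 0 in these 3 says little. With 40% of genes shifted, 3.5% of calls in the E17.5 against E12.5 design (9426 genes) fell on unshifted genes, and 81% of shifted genes were recovered. An earlier draw had used the strata's own call rates. There the same design made 230 calls, 170 of them on unshifted genes (1.87% of those; 9303 genes), against 23 of 34 in the spheroid design (6984 genes) and 13 of 90 for the slope (10242 genes). It was replaced after this was seen. The cause of these calls was not tested, and how far the calls in the real E17.5 against E12.5 comparison depend on the strata is open.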

Results

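Open chromatin was profiled by ATAC-seq, which uses a transposase to insert sequencing adapters into accessible DNA, in 32 mouse intestinal epithelial libraries of 11 groups. Cells sorted for EpCAM, an epithelial surface protein, came from embryonic days E12.5, E14.5 and E15.5 with 3 libraries each and from E17.5 with 4. Cells carrying a Bmi1-GFP reporter came from E17.5 embryos, from adults and from adults 48 h after irradiation, with 3 libraries each. Cells carrying an Lgr5-GFP reporter, a marker of crypt base stem cells, came from adults (3 libraries) and from a stage that the labels do not give (2 libraries). Cultures were represented by Bmi1-GFP spheroids (2 libraries) and Lgr5-GFP enteroids (3 libraries), which are epithelial structures grown in culture. The stage of the animals behind these cultures is not in the sample titles. Whether the libraries of a group came from separate animals or cultures is not stated, so the p-values measure the spread between these samples, which may be technical. Each library's data were a list of accessible regions, and read depth was unknown. The comparisons therefore used the call excess, in percentage points. It is the share of a gene's nearby variable regions that a library called, minus an expected share. The expected share came from that library's call rates among regions called in equally many of the compared libraries.

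List length differed 10.4-fold between libraries, from 11934 to 123763 peaks. Adult Bmi1-GFP cells had the shortest lists, at 15275 ± 5250 peaks (SD, n = 3), and Lgr5-GFP cells of unlabelled stage the longest, at 118014 ± 8130 (n = 2). EpCAM libraries held 93481 ± 4369 peaks at E12.5 (n = 3) and 70103 ± 7355 at E17.5 (n = 4), a ratio of 0.75. Adult Lgr5-GFP cells had 4.81 times as many peaks as adult Bmi1-GFP cells. Irradiated Bmi1-GFP cells had 25465 ± 19486 peaks (n = 3). Replicate 3 alone had 47957, and without it the ratio to unirradiated cells turned from 1.67 to 0.931. Among 7 exact two-sided permutation tests of peak number the smallest p was 0.0571, the lowest that 4 against 3 libraries allow, and 3 against 3 cannot go below 0.1. After adjustment over the 7 tests the smallest value was 0.2, so no pair passed, although the lists did not overlap in length in 5 of them.

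**Figure D1:**
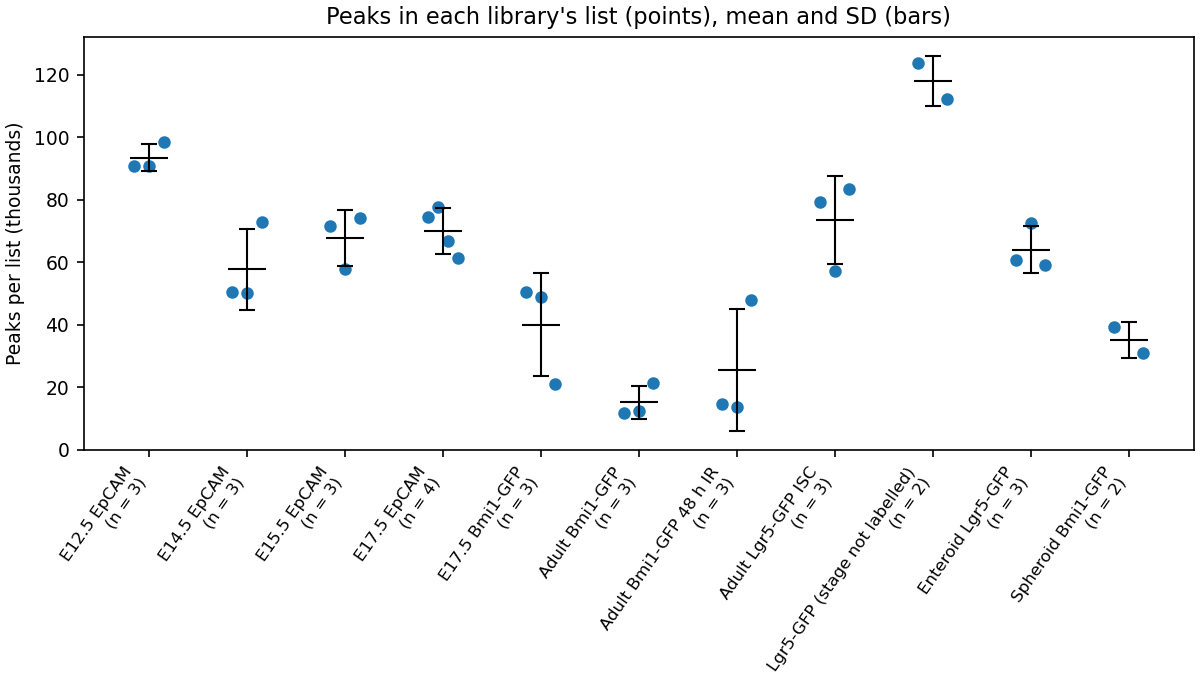
Peaks in each library's list by group. Points are libraries and bars give the mean and SD; adult Bmi1-GFP lists held 11934 to 21326 peaks and those of Lgr5-GFP cells of unlabelled stage 112265 to 123763.

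On average, libraries resembled others of their own group. Those of the E17.5 Bmi1-GFP group did so only weakly, and those of the adult Bmi1-GFP group weakly before lists were trimmed to equal length. The mean Jaccard index of called regions was 0.578 over the 32 pairs within groups and 0.347 over the 464 pairs between groups (permutation p = 1e-05, the smallest that 100000 permutations can give). After subtraction of the expected calls, the mean correlation of call residuals was 0.267 within and -0.05 between groups (permutation p = 1e-05). E12.5 epithelium correlated at 0.54 within its group, at 0.256 with E14.5, 0.074 with E15.5 and -0.22 with E17.5. Adult Lgr5-GFP cells correlated at 0.222 with Lgr5-GFP enteroids, whereas adult Bmi1-GFP and adult Lgr5-GFP cells correlated at -0.004, and at -0.106 with lists of equal length. Spheroids correlated at 0.535 with each other and at 0.043 with enteroids. E17.5 Bmi1-GFP libraries correlated at 0.054 within their group and at 0.05 with E17.5 EpCAM (0.003 and 0.025 at equal length). Adult Bmi1-GFP libraries correlated at 0.063 within their group and at 0.085 with irradiated ones (0.209 and 0.244 at equal length). At equal length E17.5 EpCAM (0.197) and E15.5 EpCAM (0.165) lay below the 0.209 within their groups, and most other groups above it. In 28 of 32 libraries the best correlated library belonged to the same group. The 4 others were adult Bmi1-GFP replicates 2 and 3, irradiated replicate 3 and E17.5 Bmi1-GFP replicate 3, each closest to another Bmi1-GFP group.

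**Figure D2:**
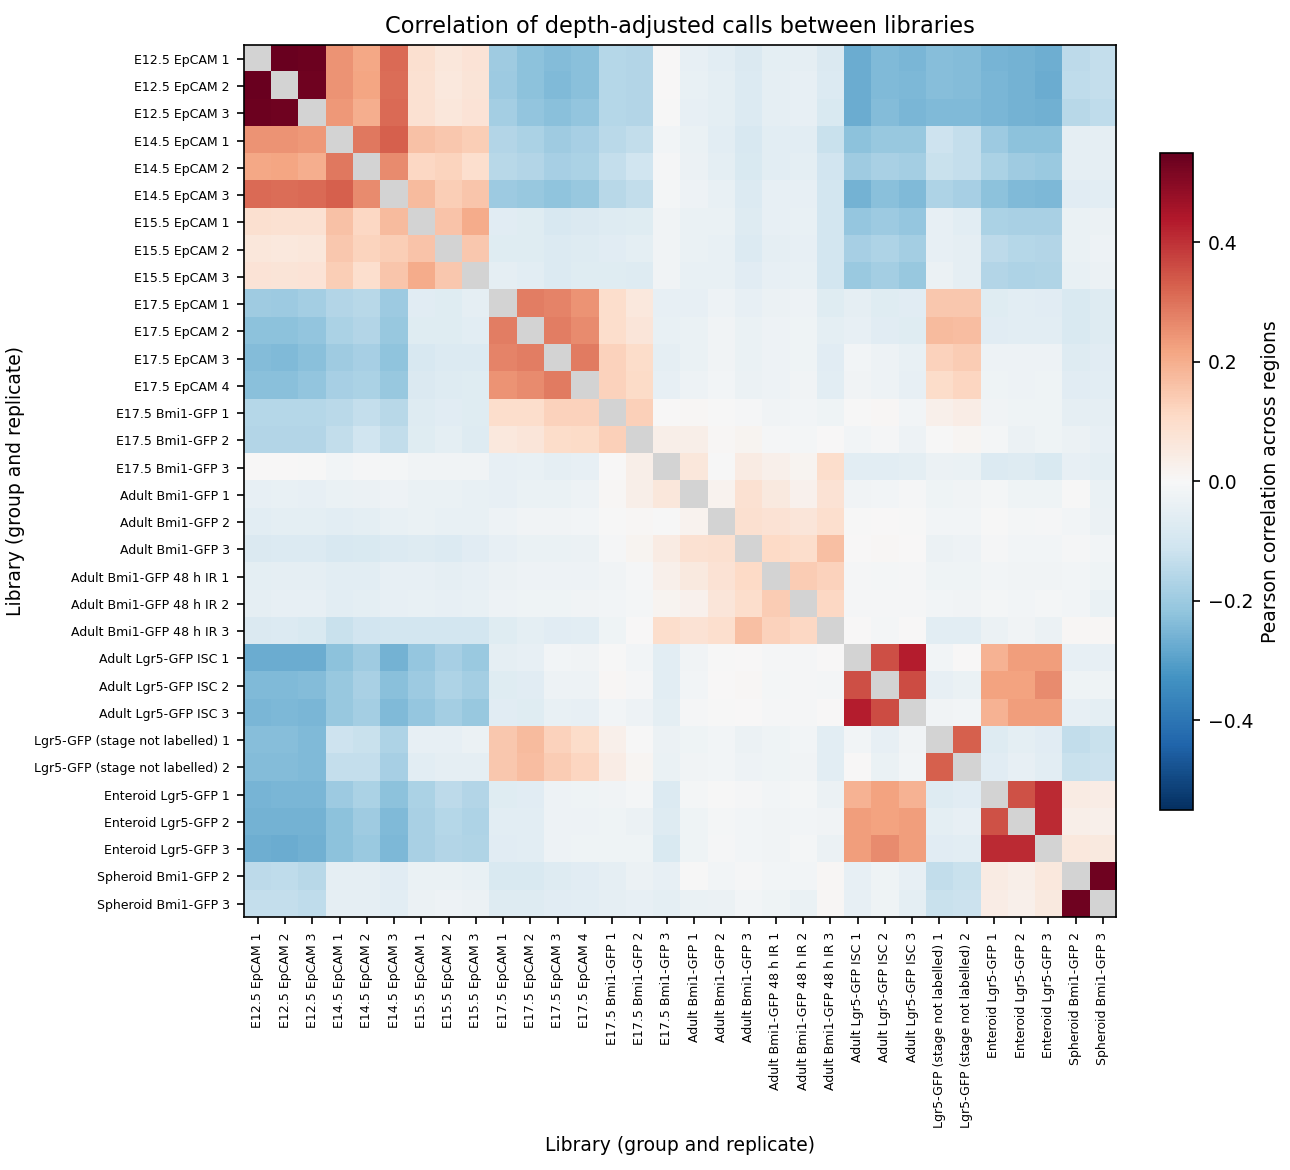
Pearson correlation across regions of call residuals between each pair of the 32 libraries, with group and replicate on both axes and the diagonal left grey. Red blocks along the diagonal mark groups whose libraries resembled each other, with means of 0.54 in E12.5 EpCAM and 0.535 in spheroids. The mean was 0.054 in E17.5 Bmi1-GFP and 0.063 in adult Bmi1-GFP. With lists of equal length, which are not drawn, these means were 0.003 and 0.209.

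Fetal epithelium at E17.5 (n = 4) was compared with that at E12.5 (n = 3). Mgam, encoding the brush border enzyme maltase-glucoamylase (chromosome 6, 40628831 to 40769123, mm10), rose by 81 ± 7.3 points (SE; adjusted p = 4.86e-09), with 9.5 ± 0.58 (SD) of its 11 variable regions called at E17.5 and 0.67 ± 0.58 at E12.5. Areg, encoding the epidermal growth factor receptor ligand amphiregulin (chromosome 5, 91139599 to 91148432), rose by 89.9 ± 9.8 points (adjusted p = 5.63e-08), with 5.5 ± 0.58 of 6 regions called at E17.5 and 0 at E12.5. The collagen gene Col3a1, a mesenchymal marker, and Hoxd3, of the Hox genes that pattern the body axis, fell (-48.1 ± 11 and -45.7 ± 9.6).

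Among the other genes with the largest gains at E17.5 were Btnl6 (89.9 points), Cdc42se2 (89.2), Sppl2a (86.2), the autophagy receptor gene Tax1bp1 (82.1), Arhgap17 (80.2) and Hectd4 (79.3). Members of the fixed lists with the largest gains were Rac1 (91.9 points), the translesion polymerase gene Polk (84.4), the cystine transporter subunit gene Slc7a9 (84.4), the glycolytic gene Pgk1 (80.5), Ugt2b34 (80.5), the peroxisomal enzyme gene Ehhadh (80), Gadd45a (78.3) and the carboxylesterase gene Ces2a (77.2). Pgk1 belonged to the housekeeping control list, of which 2 of 6 measured members rose, both over all genes and adjusted over the list alone. The largest losses were at Col22a1, a collagen gene (-73.4 ± 10, adjusted p = 1.4e-06), Elovl7 (-63.7), the neurotrophin gene Bdnf (-62), Kndc1 (-61.6), Tspan17 (-58.7), Iqcj (-58.7), Gm36079 (-58.2) and LOC115489673 (-55.9). Epcam rose by 23.7 ± 7.6 points (adjusted p = 0.0123), and Lgr5 stood at 2.0 ± 7.1 (adjusted p = 0.838).

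Enterocyte markers rose as a group: 18 of 25 measured members were higher at E17.5 over all genes, and 18 adjusted over the list alone. Mep1a (61.8 ± 9.3), the lipid transfer gene Mttp (61.6 ± 8.6), the bile acid transporter gene Slc10a2 (62.8 ± 10.1) and the peptidase gene Dpp4 (41.8 ± 5.8) were examples. The list test gave an adjusted p of 4.51e-05, and an adjusted p = 0.0697 with an estimated correlation. In lipid and bile acid metabolism 10 of 21 genes rose by either count, among them the nuclear receptor genes Ppara (69 ± 7.5) and Nr1h4 (56.7 ± 7.2); the adjusted p was 0.00553, and adjusted p = 0.107 with an estimated correlation. In xenobiotic metabolism 8 of 13 rose by either count, with Ces2c at 69.4 and Ugt1a1 at 67.7 ± 15.8; the adjusted p was 0.00553, and adjusted p = 0.132 with an estimated correlation. At equal length the gap of that list to other genes went from 33.3 to 18.8 points and did not pass. Of 16 measured gut transcription factor genes 6 rose, including Elf3 (62.5 ± 9.1), Hnf4g (51.8 ± 6.4) and Tcf7l2 (32.3 ± 4.7), and Foxa2 fell (-21.5 ± 7.0), while the list as a whole did not pass (adjusted p = 0.205).

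Hox genes fell as a group, with 12 of 18 measured members lower over all genes and 12 adjusted over the list alone. Hoxd3 stood at -45.7 ± 9.6 and Hoxb1 at -42.7 ± 9.2, and the list had an adjusted p of 4.51e-05, and an adjusted p = 0.0697 with an estimated correlation. Mesenchyme markers were lower in 11 of 23 by either count, with Twist2 at -42.2, Zeb2 at -28.4 and Col3a1 at -48.1; the adjusted p was 0.000449, and adjusted p = 0.0893 with an estimated correlation. Among markers of other cell types, 4 of 14 endothelial genes were lower (Sox17, -40). Of 11 enteric neural genes 5 were lower (Hand2, -50.3) and 2 higher (Ret, 40.7). Among 9 immune genes 3 were lower (Spi1, -54.7) and 2 higher (Itgam, 42.9). Over all 10269 genes 1860 were lower and 2379 higher, and none of these lists passed as a whole. Their counts alone therefore do not show a shift of these cell types. Enteroendocrine genes, which mark hormone-producing cells, were lower in 12 of 22 over all genes and in 13 adjusted over the list alone, including Fev (-61.7 ± 15), Sst (-51.3 ± 12.6) and Rfx6 (-27 ± 5.9). That list had an adjusted p of 0.000837, and an adjusted p = 0.0893 with an estimated correlation. Foregut and stomach markers were lower in 5 of 8 by either count, with Sox2 at -40.1 ± 7.9 and Pax9 at -44.8 ± 8.9 (adjusted p = 0.0446, and adjusted p = 0.32 with an estimated correlation). With 50% of a region covered the gap to other genes went from -25.8 to -8.19 points for the foregut list, which then did not pass, and from -34.5 to -19.1 for Hox genes.

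In limma's test 4239 of 10269 genes passed an adjusted p of 0.05, 2379 higher and 1860 lower at E17.5. At the level of single regions, 9702 were called in all E17.5 and no E12.5 libraries and 19515 in the reverse. With lists trimmed to 61368 peaks the numbers for the real groups were 10436 and 10456, and with 50% of a region covered 2270 and 13860. The excess on the E12.5 side therefore depended on the setting.

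Across the 13 EpCAM libraries the same gene groups followed embryonic day. Mgam gained 15.7 ± 1.28 points per day (adjusted p = 3.51e-15), the bile acid receptor gene Nr1h4 17.2 ± 1.31 (adjusted p = 6.14e-16) and Ces2c 20.1 ± 2.42. Zeb2 lost ground at -7.37 ± 0.93 points per day, Hoxd3 at -11.8 ± 1.85 and the endocrine factor gene Rfx6 at -8.00 ± 1.18. Enterocyte genes stood at a mean call excess of -21.6 ± 0.47 points (SD) at E12.5, -7.42 at E14.5, -0.03 at E15.5 and 21.8 ± 2.41 at E17.5. Hox genes went from 19.1 at E12.5 to 2.14, -5.3 and -12 at the later days, and mesenchyme genes from 17.6 to -0.15, -4.31 and -9.85.

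Over embryonic day 20 of 26 enterocyte genes rose, both over all genes and adjusted over the list alone (adjusted p = 2.11e-06, and adjusted p = 0.00298 with an estimated correlation). In lipid and bile acid metabolism 15 of 22 rose and 1 fell, and in xenobiotic metabolism 11 of 15 rose and 1 fell, with the same numbers adjusted over the list alone; both lists had an adjusted p = 0.0219 with an estimated correlation. Falling genes were 15 of 24 in mesenchyme by either count, 13 of 18 in Hox genes (14 adjusted over the list alone) and 15 of 24 in enteroendocrine genes (17 adjusted over the list alone, with 1 rising). These held with an estimated correlation at adjusted p = 0.0494, 0.0494 and 0.0219. In the Hedgehog pathway 7 of 11 genes fell by either count, with Gli2 at -5.75, Ptch1 at -7.91 and Boc at -10.6 points per day (adjusted p = 0.0235, and adjusted p = 0.0658 with an estimated correlation). The gap of the Hedgehog list to other genes, -4.63 points per day, was -0.97 at equal length and -1.45 with the top 50% of peaks, and passed in neither. Foregut and stomach genes fell in 5 of 9 (6 adjusted over the list alone) with 1 rising (adjusted p = 0.0312, and adjusted p = 0.0776 with an estimated correlation), and their gap of -5.37 was -2.41 with 50% of a region covered and did not pass. In the antimicrobial list 5 of 11 rose (6 adjusted over the list alone), among them the lectin gene Reg3g at 13.2 ± 1.34 points per day, and the receptor gene Tlr4 fell at -4.73 ± 1.54 (adjusted p = 0.048, and adjusted p = 0.245 with an estimated correlation); the list's gap of 5.47 was 3.73 with the top 50% of peaks and did not pass.

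The slope passed in 5431 of 11140 genes by limma, 3038 gained and 2393 lost. Of the 5431 genes 3743 also passed between E12.5 and E17.5, a comparison that shares its libraries. Between neighbouring days, 116 genes passed from E12.5 to E14.5 (114 higher, 2 lower; 100 and 63 with lists of equal length) and 50 from E14.5 to E15.5 (14 higher, 36 lower; 21 and 11 at equal length). From E15.5 to E17.5 1244 genes passed (695 higher, 549 lower; 456 and 359 at equal length).

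**Figure D3:**
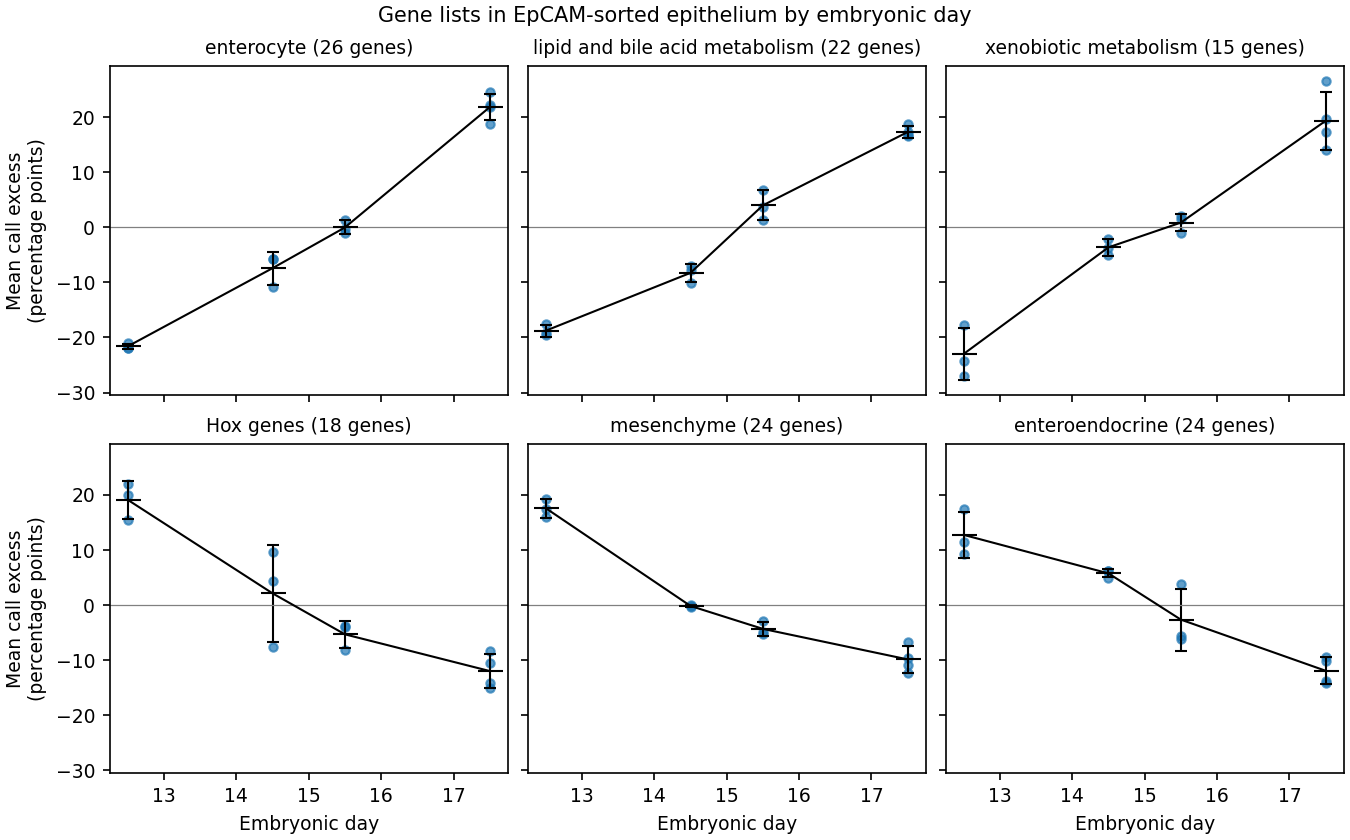
Mean call excess of the measured genes of 6 lists, in percentage points, against embryonic day in EpCAM-sorted epithelium. Points are libraries, and bars and lines give the mean and SD; enterocyte genes went from -21.6 at E12.5 to 21.8 at E17.5 and Hox genes from 19.1 to -12.0.

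At E17.5, Bmi1-GFP cells (n = 3) were set against EpCAM-sorted epithelium (n = 4) to ask which accessible regions mark the reporter-positive cells. Pde1c, encoding a cyclic nucleotide phosphodiesterase (chromosome 6, 56069798 to 56652510), rose by 65.5 ± 8.2 points (adjusted p = 7.29e-05), with 6.0 ± 1.0 of 11 variable regions called in Bmi1-GFP and 2.75 ± 1.89 in EpCAM libraries. Next came Nek10 (58.2 ± 11.5), the G protein signalling regulator gene Rgs17 (53.9 ± 11.5), the transcription factor gene Foxp2 (51.4 ± 10.7), Rab12 (49.5 ± 9.6), the G protein subunit gene Gng4 (49.3 ± 9.5), Cntnap4 (46.7 ± 10.1) and Fam172a (40.6 ± 8.1).

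Enteroendocrine genes lay above the other genes in Bmi1-GFP cells: 12 of 15 measured members had positive differences, none passed over all genes and 5 passed adjusted over the list alone. The prohormone convertase gene Pcsk1 stood at 44.5 ± 11.4 (adjusted p = 0.11), Rfx6 at 37 ± 9.8 (0.126), Rimbp2 at 40.2 ± 10.8 (0.129) and Neurod1 at 46.4 ± 15.2 (0.277). The list test gave an adjusted p of 2.36e-05, and an adjusted p = 0.692 with an estimated correlation. Toward EpCAM, the genes with the smallest p did not pass: Cpne8 at -22 ± 6.7 (adjusted p = 0.217), Dis3l2 at -26.3 ± 8.1 (0.232) and Tacc2 at -16.8 ± 5.2 (0.24). Epcam (-10.8 ± 9.4) and Lgr5 (10.5 ± 9.2) did not pass either. By limma 22 of 8617 genes passed, all higher in Bmi1-GFP cells. The number depended on single libraries: it was 0 without Bmi1-GFP replicate 2, 1 without EpCAM replicate 4, 7 without Bmi1-GFP replicate 3, 9 without Bmi1-GFP replicate 1 and 11 without EpCAM replicate 1. It was also 0 with lists of equal length.

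Adult Bmi1-GFP cells (n = 3) and adult Lgr5-GFP stem cells (n = 3) were compared as the reporter populations of the adult crypt. At the Lgr5 gene itself (chromosome 10, 115450314 to 115587780), Lgr5-GFP libraries called 10.3 ± 2.89 of 14 variable regions and Bmi1-GFP libraries 0. The strata predicted 0.32 calls in Bmi1-GFP libraries (difference -4.6 ± 4.9 points, adjusted p = 0.865). In all Lgr5-GFP and no Bmi1-GFP libraries 26968 regions were called, and this difference is part of the prediction. The small value therefore does not show that list length accounts for the missing calls at Lgr5. Epcam stood at 5.4 ± 8.7. The genes with the smallest p were Slc12a1 (79.8 ± 12.1), Sgip1 (47.8 ± 8.7) and Eml6 (50.4 ± 9.5) toward Bmi1-GFP and Esrrg (-4.7 ± 2.7), Rabgap1l (-4.3 ± 2.6) and Ptprm (-4.6 ± 2.9) toward Lgr5-GFP, all with an adjusted p of 0.865. At Slc12a1 both groups called 2.0 ± 1.0 of 4 regions, where the strata predicted 0.4 and 3.6. By limma 0 of 8734 genes passed, with 180 at an unadjusted p under 0.05, all higher in Bmi1-GFP cells. That number is below the share of 0.05 that chance alone would give. Excess is easier to detect in the group with shorter lists, so its direction cannot be read as a lean toward Bmi1-GFP cells.

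In that comparison enteroendocrine genes lay above the other genes in Bmi1-GFP cells, with 8 of 14 measured members positive, 0 passing over all genes and 4 adjusted over the list alone. Neurod1 stood at 61.7 ± 14.9 points and Pax4 at 39.9 ± 12.6, and the list had an adjusted p of 6.98e-05, and an adjusted p = 0.682 with an estimated correlation; as log2 of covered length its mean lay at -0.45 relative to other genes, and with 50% of a region covered the gap went from 13.8 to 3.72 points and did not pass. Tuft cell genes were positive in 9 of 11, with Alox5 at 38.1 ± 18.7 and the kinase gene Dclk1 at 17 ± 10.5, and 0 passed by either count, including adjusted over the list alone (adjusted p = 0.00058, and adjusted p = 0.682 with an estimated correlation). With the top 50% of peaks the gap of the tuft list went from 11 to 3 points, and as log2 of covered length it was 0.50, and it passed in neither. Mesenchyme markers were positive in 10 of 14, with Foxf2 at 28.3 ± 10.2 and Col1a1 at 19.5 ± 13.1, and again 0 passed by either count, including adjusted over the list alone (adjusted p = 0.00058, and adjusted p = 0.682 with an estimated correlation). Their mean turned to -1.13 relative to other genes as log2 of covered length and to -2.74 points with the top 50% of peaks. At equal length all 3 lists had too few measured genes for a test.

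With lists trimmed to 11828 peaks, 75 genes passed between adult Bmi1-GFP and Lgr5-GFP cells, 16 higher and 59 lower in Bmi1-GFP. As log2 of covered length 6282 passed, 3037 higher and 3245 lower. That setting is scaled to total covered length but subtracts no expected calls. Adult Lgr5-GFP lists held 4.81 times as many peaks, so the 6282 cannot be read apart from list length. At equal length Mgam (-52.7 ± 8.8, adjusted p = 0.0338), the bicarbonate transporter gene Slc4a4 (-61.6 ± 10.7) and the transcription factor gene Sox5 (-50.1 ± 8.8) were lower in Bmi1-GFP cells, and Mtss1 (60.6 ± 10.2) and Sfi1 (50.4 ± 10.3) higher. Before trimming, 26968 regions were called in all Lgr5-GFP and no Bmi1-GFP libraries and 40 in the reverse. With equal length they were 1531 and 713. Other splits of the same libraries gave at most 665 regions on either side before trimming.

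Irradiation of the adult Bmi1-GFP cells (n = 3 in each state, 48 h) gave no gene past the threshold. Toward irradiated cells, the smallest p belonged to Syt11 (48.9 ± 11.8), Mn1 (47.3 ± 12) and Csrp1 (41.7 ± 10.7). In the other direction they belonged to Clca2 (-61.5), Pter (-53.3 ± 12.6) and Cmya5 (-55.3 ± 13.4), all 6 with an adjusted p of 0.387. Epcam stood at 25.3 ± 9.0 (adjusted p = 0.506) and Lgr5 at 23 ± 12.7 (0.584), the latter with 1.33 ± 1.53 of 3 regions called after irradiation and 0 before. Among the listed genes the death receptor gene Tnfrsf10b, a p53 target, stood at 33.5 ± 12.1, and the transcription factor genes Gata6 and Elf3 at -45.1 ± 11.8 and 31 ± 8.4. All 5 measured fetal spheroid markers were positive, with Basp1 at 13.9 ± 6.8, but that list did not pass (adjusted p = 0.466), nor did any other. By limma 0 of 4607 genes passed, with 339 at an unadjusted p under 0.05, 154 higher and 185 lower. The 339 are above the share of 0.05 that chance alone would give, and other splits were not counted this way. The simulated irradiation design recovered 0 shifted genes in both directions. A count of 0 therefore does not show that irradiation had no effect. With 50% of a region covered 1 gene passed, 2 without unirradiated replicate 1, and 0 at equal length and as log2 of covered length.

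Genes that distinguish E17.5 EpCAM epithelium from adult Lgr5-GFP cells, groups that differ in stage and sort together, were followed through irradiation. Of 1056 genes higher in E17.5 EpCAM than in adult Lgr5-GFP cells, 457 were measured in the Bmi1-GFP libraries, and 270 of them had positive differences after irradiation. Their mean difference was 1.29 points, against 0.86 for other genes (p = 0.839, and p = 0.909 with an estimated correlation). The gap of 0.43 turned to -0.91 without unirradiated replicate 3, -0.77 without irradiated replicate 3, -0.1 without E17.5 EpCAM replicate 1, -0.1 without adult Lgr5-GFP replicate 2 and -0.04 without adult Lgr5-GFP replicate 3. Of 901 genes higher in adult Lgr5-GFP cells 509 were measured, at -1.58 points relative to other genes (p = 0.31, and p = 0.379 with an estimated correlation). With lists of equal length the sets were themselves different and few of their genes were measured: 69 of 738 higher in E17.5 EpCAM lay at 1.63 points (p = 0.541, and p = 0.478 with an estimated correlation) and 123 of 683 higher in adult Lgr5-GFP cells at -5.87 (p = 0.0438, and p = 0.044 with an estimated correlation), among 991 genes.

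Adult Bmi1-GFP cells (n = 3) were also set against E17.5 Bmi1-GFP cells (n = 3). Tuft cell genes lay above the other genes in the adult, with 7 of 7 measured members positive. Ptgs1, encoding a prostaglandin synthase, stood at 45.9 ± 16.2 points, Dclk1 at 28.9 ± 12.8, Plcg2 at 27.8 ± 13.5 and Sh2d6 at 24.7 ± 11.1, and 0 of them passed over all genes or adjusted over the list alone. The tuft list gave an adjusted p of 4.97e-05, and an adjusted p = 0.892 with an estimated correlation; at equal length and with the top 50% of peaks too few of its genes were measured for a test, and with 50% of a region covered the gap went from 23.5 to 37.4 points on 3 members. Mesenchyme markers were positive in 6 of 7 as well, with a median of 13.4 points and 1 passing adjusted over the list alone, but that list did not pass (adjusted p = 0.31, and adjusted p = 0.892 with an estimated correlation). The genes with the smallest p were Clec14a (80 ± 17), Marchf1 (43.6 ± 9.9) and Trappc9 (42.6 ± 9.8) toward the adult, with an adjusted p of 0.377, and Med15 (-31.5 ± 12.8), Amotl2 (-27 ± 11.6) and Samd4 (-23.8 ± 10.3) toward E17.5, with an adjusted p of 0.903. Lgr5 stood at -15.3 ± 10.3 and Epcam at -13.2 ± 11.5. By limma 0 of 6357 genes passed, at equal length 0 and as log2 of covered length 0. At an unadjusted p under 0.05 there were 205, 193 higher and 12 lower in the adult. That number too is below the share of 0.05 that chance alone would give. The adult lists were shorter on average, so its direction cannot be read as a lean toward the adult.

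In culture, Bmi1-GFP spheroids (n = 2) differed from Lgr5-GFP enteroids (n = 3) in 483 of 8020 genes by limma, 429 higher and 54 lower in spheroids. Ptgs2, encoding the inducible prostaglandin synthase (chromosome 1, 150100031 to 150108234), rose by 90.5 ± 11.1 points (adjusted p = 0.0012), with 5.5 ± 0.71 of 7 regions called in spheroids and 0.33 ± 0.58 in enteroids. The atypical cadherin gene Fat3 rose by 88.4 ± 8.9 (adjusted p = 0.000662), with 11 ± 1.41 of 13 regions called in spheroids and 0 in enteroids. Other large gains were at Ttc8 (98.2), Shisal1 (96.8), Gnat3 (89.3), Sspn (89.3), Gm30679 (88.6) and the serotonin receptor gene Htr1f (87.2). Lower in spheroids were the homeobox gene Pbx3 (-51.6 ± 11.4, adjusted p = 0.017), Gm3646 (-49.5), Gas8 (-48), Tamm41 (-43), Tent5c (-42.9), BC035044 (-42.4), Pdcl3 (-42.4) and Stox2 (-42.3).

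Fetal spheroid and regeneration markers were higher in spheroids in 5 of 17 measured genes, and in 5 adjusted over the list alone. Among them were Basp1 (81.2 ± 8.5), S100a6 (57.8 ± 13.8), Spp1 (52.1 ± 13.7) and Anxa1 (42.9 ± 11.5); the list as a whole did not pass (adjusted p = 0.295, and adjusted p = 0.651 with an estimated correlation). Of 20 intestinal stem cell genes 0 passed by either count, including adjusted over the list alone, and 4 were positive. Lgr5 stood at -23.5 ± 9.2 (adjusted p = 0.139) and Smoc2 at -24.1 ± 8.3 (0.1). At Lgr5 spheroids called 0.5 ± 0.71 of 13 regions and enteroids 10.3 ± 2.31. The simulated spheroid design recovered 0 of 47 genes shifted down at an odds ratio of 16. Regions called only in enteroids also entered the prediction. The count of 0 therefore does not show that stem cell genes were alike in the 2 cultures. YAP and TEAD target genes were higher in 2 of 17 (3 adjusted over the list alone), Wwc1 at 44.1 ± 9.0 and Asap1 at 33.8 ± 7.3, with an adjusted p of 0.295 for the list. Among non-canonical Wnt genes 2 of 21 rose (6 adjusted over the list alone), Celsr1 at 45.6 ± 9.3 and Rspo3 at 59.5 ± 15.8, and the Wnt effector gene Tcf7l2 fell (-28.8 ± 6.3, adjusted p = 0.0169). Listed genes of other cell types and pathways also rose, namely Ikzf1 (119 points), Polk (90.9), Meox2 (75.5), Eda2r (72.6), Grem1 (72.6), Stmn2 (72.6), Tlr4 (67.6) and Flt1 (65.2). Epcam stood at -8.0 ± 14.9.

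With equal length 499 genes passed, 315 higher and 184 lower, and as log2 of covered length 5280, 2034 higher and 3246 lower. The number was 0 without either spheroid library (replicate 2 or 3), 1061 without enteroid replicate 1 and 1102 without enteroid replicate 3; leaving out a spheroid library leaves 1, so the spread then comes from enteroids alone. Before trimming 6464 regions were called in both spheroid and no enteroid libraries and 20088 in the reverse. At equal length they were 7546 and 7851. Other splits of the same libraries, before trimming, gave at most 4880 on the side of 2 libraries and 529 on that of 3. The spheroid side therefore stood out less than the enteroid side. Other splits were not counted at equal length.

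**Figure D4:**
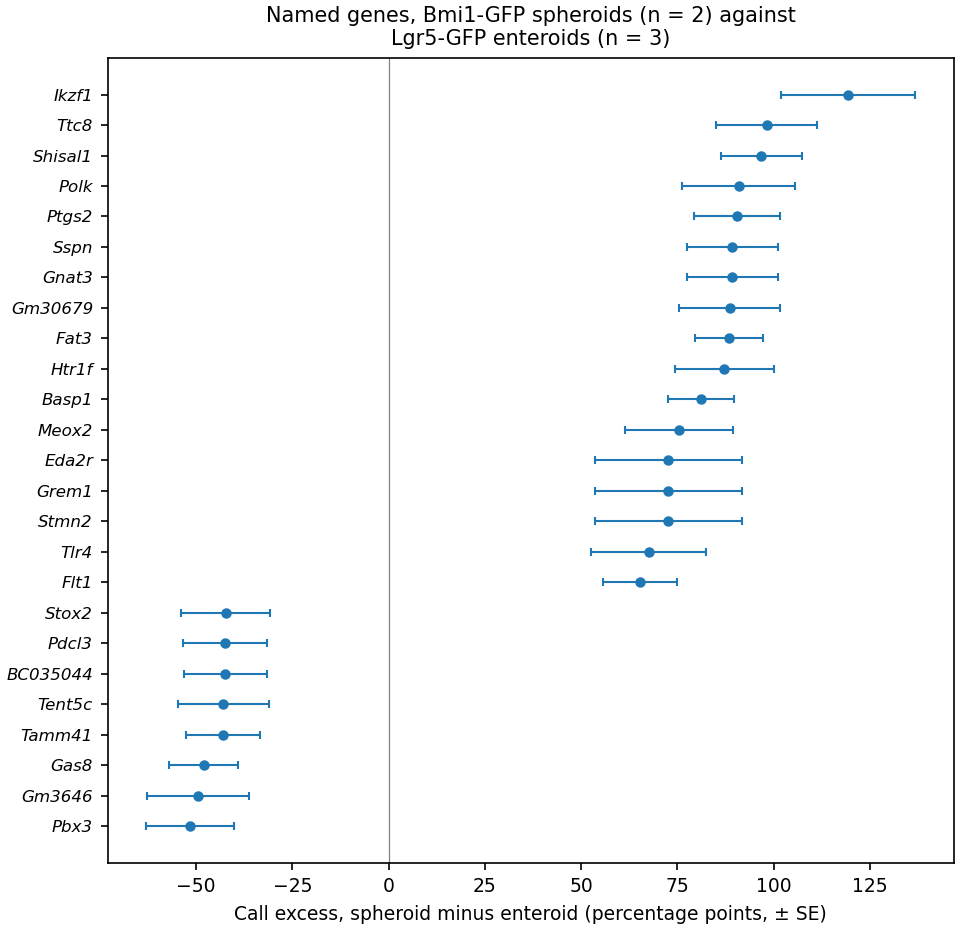
Difference in call excess between Bmi1-GFP spheroids (n = 2) and Lgr5-GFP enteroids (n = 3), in percentage points with SE, for genes past the threshold with the largest differences. Points right of 0 were higher in spheroids, from 65.2 at Flt1 to 119 at Ikzf1, and points left of 0 lower, down to -51.6 at Pbx3.

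Adult Lgr5-GFP stem cells (n = 3) were compared with Lgr5-GFP cells of unlabelled stage (n = 2). Cyp3a11, a cytochrome P450 gene (chromosome 5, 145854607 to 145879854), rose by 131 ± 17.7 points (adjusted p = 2.79e-05), with 2.67 ± 0.58 of 3 regions called in the adult and 0 in the other group. Its relatives Cyp3a25 (109 ± 13.6) and Cyp3a59 (91.4 ± 13.5) rose too. Further large gains were at Ky (113 ± 12.4, adjusted p = 2.92e-06), the urea transporter gene Slc14a1 (103), Il1rap (94.9), D10Wsu102e (94.4), Fundc1 (93.3) and Cap2 (92.4). Lower in the adult were Pde2a (-29.9 ± 8.1, adjusted p = 0.0325), Lypd6 (-29.7), Arhgef10l (-28.4), Skap1 (-27.5), the homeobox gene Meis1 (-26.8), Opcml (-26), Snx9 (-25.8) and Ltbp1 (-25.6).

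Listed genes higher in the adult were the goblet cell gene Spink4 (98.8), Nod2 (87), Sox10 (79.1), Ada (77.5), the stem cell marker Rgmb (71.5 ± 11.1), Phc1 (71.2), the Wnt target Nkd1 (61.8) and Sox17 (61.6). Canonical Wnt targets rose in 3 of 19, both over all genes and adjusted over the list alone, with Lef1 at 38.9 ± 9.6 and Ephb3 at 40.6 ± 11.1 beside Nkd1. In xenobiotic metabolism 2 of 15 rose (4 adjusted over the list alone), and of 4 measured class II antigen presentation genes Ciita rose (46 ± 12.9), with 2 passing adjusted over the list alone. No list as a whole passed; the smallest adjusted p was 0.194. Lgr5 stood at 9.2 ± 8.6 and Epcam at -11.9 ± 12.4. By limma 387 of 9840 genes passed, 368 higher and 19 lower in the adult. The number was 211 without replicate 1 of the unlabelled stage and 48 without replicate 2, each of which leaves 1 library there and takes the spread from the adult alone, and the split was 129 higher and 106 lower at equal length and 840 and 1355 as log2 of covered length.

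The Bmi1 gene, which names the reporter, had 2 regions within reach and too few variable ones for a test in any comparison. Adult and E17.5 Bmi1-GFP libraries each called 0.67 ± 0.58 of the 2 (n = 3), adult Lgr5-GFP libraries 1 and E12.5 libraries 1.33 ± 0.58 (n = 3).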

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

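The tests of culture against adult tissue, of pooled markers of other cell types, the share of matched random lists and the regrouping of libraries were chosen after the first results were seen. The difference between Bmi1-GFP and Lgr5-GFP groups was itself different in culture and in adult tissue, in 234 of 10462 genes by limma. It was larger in culture in 114 and smaller in 120, and at equal length larger in 121 and smaller in 24. In culture, reporter and culture form (spheroid or enteroid) changed together. The ratio of Bmi1-GFP to Lgr5-GFP peak numbers also differed, at 0.208 in adult tissue and 0.549 in culture. These genes therefore cannot be assigned to the reporter. The matrix metalloproteinase gene Mmp7 stood at -29.3 points in adult tissue and 62.2 in culture (difference 91.5 ± 19, SE, adjusted p = 0.0123; n = 3 and 3 adult, 2 and 3 cultured libraries). Bmp4 stood at -6.4 and 57.4 (63.8 ± 15.8, adjusted p = 0.0278) and Basp1 at 12.1 and 53 (40.8 ± 8.6, adjusted p = 0.0126). With spheroids and enteroids compared alone, Basp1 stood at 81.2, since call excess depends on the libraries compared. The brush border gene Vil1 stood at 7.5 and -45.5 (-53.1 ± 11.7, adjusted p = 0.0144). Pck1, a gluconeogenic gene, stood at 30.3 and -55 (-85.3 ± 18.4, adjusted p = 0.0135). The housekeeping control gene Pgk1 moved as far, from 37.3 to -53.1 (-90.4 ± 17.6, adjusted p = 0.0097). The listed gene Ikzf1 stood at 15.7 and 105.8 (90 ± 19.4, adjusted p = 0.0135). The number was 80, 77 and 38 without adult Bmi1-GFP replicates 1, 2 and 3, 154, 88 and 155 without adult Lgr5-GFP replicates 1, 2 and 3, 123 without enteroid replicate 2, and 60 and 136 without spheroid replicates 2 and 3.

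A signal outside the compared data was found in 62651 merged regions that lie in no library's own list and come from the per-group lists alone. Peaks on chromosome Y, which entered no comparison, were most frequent in enteroid replicate 1, at 263.

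Enteroendocrine genes lay above other genes in E17.5 Bmi1-GFP cells, and list length and gene size were weighed against a share of endocrine cells among the reporter-positive ones. The list call (adjusted p = 2.36e-05) was lost with an estimated correlation (adjusted p = 0.692). With lists of equal length the 5 members still measured lay 23.9 points above other genes (p = 0.00564, and p = 0.0956 with an estimated correlation). List length as the whole cause would have put them at or below other genes. With 5 of 15 members measured and no pass with an estimated correlation, whether it was the whole cause stays open. Random lists matched for gene span and number of variable regions had a mean of -2.07, the middle 95% of them between -8.81 and 5.54, against 19.1 for the 15 members. The share of random lists as far out was 1e-04, the smallest that 10000 lists can give, which speaks against gene size as the cause, but random lists do not carry the correlation among the members. A biological cause, more cells of endocrine fate among Bmi1-GFP cells, may remain, but no gene of the list passed over all genes.

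Mesenchyme genes were lower at E17.5 than at E12.5 in libraries sorted for EpCAM, a sort that should remove mesenchymal cells (adjusted p = 0.000449, and adjusted p = 0.0893 with an estimated correlation). With lists of equal length the 14 members still measured lay at -26.9 points relative to other genes (p = 0.00226, and p = 0.0228 with an estimated correlation), and the share of matched random lists as far out was 1e-04, which speaks against list length and gene size as the whole cause, with the same limit of random lists. More cells of other types at E12.5 would lower other markers too, and 46 pooled markers of endothelium, smooth muscle, immune, enteric neural and blood cells lay at -11.7 points (p = 0.0253, and p = 0.0432 with an estimated correlation), as that explanation needs. E12.5 libraries called 3.33 ± 1.53 of 6 variable regions at Col1a1, 4 of 5 at Col3a1 and 16.7 ± 1.15 of 26 at Zeb2 (n = 3), and only 1 of the 24 mesenchyme genes is in another list. Carried-over cells therefore remain a candidate explanation beside a change within epithelial cells, and the lists cannot separate them.

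List length was weighed as a cause of the genes higher in spheroids than in enteroids. With equal length 315 genes were called higher, against 429 before; 177 of the 429 (41.3%) were among those still called higher, and 391 of the 396 still measured kept their sign. List length therefore bears on which genes pass, and how far it accounts for their number is open. Pooled markers of other cell types lay 5.55 points above other genes in spheroids (p = 0.4, and p = 0.387 with an estimated correlation; 45 markers), which cannot tell whether such cells were present. Culture form and reporter differ together between the 2 groups, so a biological cause cannot be assigned to either.

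Regrouping the same libraries asked only whether other groupings gave as many genes. It cannot show how far the counts depend on the strata, because a group difference within strata follows the real grouping. In the earlier simulated draw for E17.5 against E12.5, 170 of 230 calls fell on unshifted genes, and regrouping does not bear on this. Of 35 splits, 1, the real one, gave as many genes as E17.5 against E12.5 EpCAM (4239, at most 559 in another split), as E17.5 Bmi1-GFP against EpCAM (22, at most 3) and as E17.5 EpCAM against adult Lgr5-GFP cells (1957, at most 392). For embryonic day 1 of 100 orders, the real one, reached 5431, and the highest other had 2062. The 10 splits of 3 against 3 libraries are too few for a share under 0.05; the real and the highest other number were 0 and 0 for adult Bmi1-GFP against Lgr5-GFP, 0 and 0 for irradiation, and 0 and 1 for adult against E17.5 Bmi1-GFP, and all 10 splits reached the real number.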

How the results depend on the processing

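Alternatives for the steps between days, for culture against tissue, for E17.5 EpCAM against adult Lgr5-GFP cells and for list directions were chosen after the first results were seen. Of 93 results under other settings 58 kept their call and size, 34 moved and 1 grew stronger; with 1 library left out 112 of 141 held, 23 moved and 6 reversed; of 609 values of named genes 487 held, 119 weakened and 3 reversed. The slope on embryonic day, with 5431 genes, gave 3832 at equal length, and library similarity kept its direction (differences of 0.146 and 0.316 at equal length). Called lists kept their direction wherever a setting left enough genes to test, apart from enteroendocrine and mesenchyme genes in adult Bmi1-GFP cells. The 3 lists called there could not be tested at equal length, nor the tuft list against E17.5 Bmi1-GFP at equal length or with the top 50%. Of 21 list calls 6 held with an estimated correlation. Read depth is unknown, and short lists limit what can be called in the adult Bmi1-GFP groups. As log2 of covered length no expected calls are subtracted, so list length can enter those counts directly. Motif content was not run, for want of a genome. For every value below the cause was not tested.

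E17.5 against E12.5 EpCAM, with 4239 genes, gave 2658 with the top 50% of peaks, 2026 with 50% of a region covered (1406 higher, 620 lower) and 8307 as log2 of covered length; LOC115489673 turned to 0.907 with the top 50%. E17.5 Bmi1-GFP against EpCAM, with 22, gave 0 at equal length, 4 with the top 50%, 9 with 50% covered and 0 as log2 of covered length; Fam172a turned to -22.5 with the top 50%, and 1 library left out gave 0 to 24. Adult Bmi1-GFP against Lgr5-GFP, with 0, gave 75 at equal length and 6282 as log2 of covered length. Irradiation, with 0, gave 1 with 50% covered and 0 to 2 with 1 library left out. Spheroids against enteroids, with 483, gave 205 with the top 50%, 5280 as log2 of covered length and 0 to 1102 with 1 library left out. Adult Lgr5-GFP against the unlabelled stage, with 387, gave 235 at equal length, 660 with 50% covered (541 higher, 119 lower), 2195 as log2 of covered length and 48 to 514 with 1 library left out; Opcml turned to 3.11 with the top 50%.

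Regions called in all libraries of 1 group and none of the other, in the same order, numbered 16130 with 50% covered; 529 at equal length and 1679 with 50% covered; 2244 and 13602; 199 with 50% covered for irradiation; 426 and 264 for adult against E17.5 Bmi1-GFP; 15397 and 14980 for spheroids; and 12091 at equal length for the unlabelled stage. The slope of mesenchyme genes relative to other genes went from -6 to -3.4 with the top 50% and -3.97 with 50% covered, and that of Hox and enteroendocrine genes from -6.83 to -4.01 and from -5.78 to -3.45 with 50% covered. The steps to E15.5 and E17.5 gave 32 and 815 genes at equal length. Adult-side genes after irradiation moved to -5.87 and fetal-side genes to 1.63 at equal length, and fetal-side genes ranged from -0.91 to 0.93 with 1 library left out, reversing at -0.91, -0.77, -0.1, -0.1 and -0.04. E17.5 EpCAM against adult Lgr5-GFP ranged from 1165 (without adult Lgr5-GFP replicate 3) to 1960 genes, with 1304 without adult Lgr5-GFP replicate 1. Culture against adult tissue gave 145 at equal length (121 larger, 24 smaller) and 38 to 249 with 1 library left out. The peak ratio after irradiation ranged from 0.931 (without irradiated replicate 3) to 2.08.

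With the replicate number as a replicate block, 1 gene passed for E17.5 Bmi1-GFP against EpCAM, 1 for adult Bmi1-GFP against Lgr5-GFP, 4 for adult against E17.5 Bmi1-GFP and 949 for spheroids (617 higher, 332 lower). It moved no other count by over 1.5 times. Samples sharing a number correlated at -0.196 to 0.079, not every one best with its own number, so nothing in the data pairs them.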

Other observations

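The tests of spheroids against fetal gene sets, the opposite sets and the single genes named here were chosen after the first results were seen. E17.5 EpCAM epithelium (n = 4) and adult Lgr5-GFP cells (n = 3) were compared to define the fetal and adult gene sets. The 2 groups differ in stage and in sort together, and stem cell genes distinguished them. Of 20 intestinal stem cell genes 11 were lower in E17.5 epithelium over all genes, and 13 adjusted over the list alone, with 1 higher. They included Ascl2 (-64.7 ± 17.4 points, SE, adjusted p = 0.00264), Rgmb (-39.8 ± 9.4), Smoc2 (-30.4 ± 8.2), Olfm4 (-26.4 ± 8.6) and Lgr5 (-22.7 ± 8.6, adjusted p = 0.0397), and the list had an adjusted p of 0.00425, and an adjusted p = 0.351 with an estimated correlation. Canonical Wnt targets were lower in 10 of 18 over all genes and in 10 adjusted over the list alone, with 2 higher; Nkd1 stood at -51.4 ± 11.3, Lef1 at -37.7 ± 9.4 and Myc at -36.9 ± 10.5 (adjusted p = 0.0265, and adjusted p = 0.536 with an estimated correlation). With the top 50% of peaks that list's gap to other genes went from -18.6 to -10.9 points and did not pass. Of 8 Paneth cell genes 4 were lower, 5 adjusted over the list alone, among them Fgfr3 (-45.6 ± 12.2) and Mmp7 (-53.2 ± 17.4), with an adjusted p of 0.019, and an adjusted p = 0.351 with an estimated correlation; the gap went from -34.1 to -14.8 with 50% of a region covered and did not pass. Higher in E17.5 epithelium were the growth factor gene Igf2 (46.4 ± 11.3), the oncofetal RNA-binding protein gene Igf2bp3 (34.3 ± 8.2), and the liver genes Fgb (72.7 ± 17.4) and Afp (52.7 ± 17.4). By limma 1957 of 8753 genes passed, 1056 higher and 901 lower at E17.5, with 1304 and 1165 without adult Lgr5-GFP replicates 1 and 3.

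With lists of equal length the genes that passed in the spheroid comparison included Schip1 (60.5 ± 5.2 points, adjusted p = 0.014), Npnt (69.8 ± 9.0), Socs6 (68.3 ± 9.9) and Sema4f (82.7 ± 12.3) toward spheroids. Toward enteroids they included the chromatin protein gene Hmga2 (-66.9 ± 6.2, adjusted p = 0.0145), Sox6 (-68.1 ± 10.3), the neuropeptide receptor gene Vipr1 (-69.1 ± 9.1) and Klhl25 (-87.5 ± 12.8).

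Spheroids were compared with gene sets drawn from other libraries, 1 pair of which differs in stage and sort together. Genes higher in E17.5 EpCAM than in adult Lgr5-GFP cells lay 6.69 points above other genes in spheroids against enteroids (744 genes, p = 0.0137, and p = 0.00635 with an estimated correlation), with 47.6% positive against 38.8% of others. At equal length the gap was 11.1 (p = 0.00129, and p = 0.0194 with an estimated correlation). Genes higher at E12.5 than at E17.5 lay 9.69 points above (1111 genes, p = 6e-04, and p = 0.00231 with an estimated correlation), 50.4% positive against 37.8%, and 17.3 at equal length (p = 4.4e-08, and p = 0.00974 with an estimated correlation). The opposite sets lay at -4.82 (p = 0.106) and -6.45 (p = 0.0133, and p = 0.135 with an estimated correlation). The medians of the 2 fetal sets were -1.74 and 0.21, against -8.77 and -9.34 for other genes. Some other values ran the opposite way. Of 7 measured Hox genes 0 were positive in spheroids (mean -22.6, adjusted p = 0.295, and adjusted p = 0.651 with an estimated correlation), and of 7 oncofetal and growth genes 2 were (mean -15.7, adjusted p = 0.358, and adjusted p = 0.651 with an estimated correlation), with Igf2bp3 at -23.5 ± 7.9 (adjusted p = 0.0947). Over all regions spheroids correlated at -0.071 and enteroids at -0.044 with E17.5 EpCAM epithelium (-0.101 and -0.016 at equal length), also the opposite way. With E12.5 EpCAM epithelium they correlated at -0.14 and -0.26 (-0.118 and -0.197 at equal length), the same way as the gene sets. Whether spheroids lie closer to fetal epithelium therefore stays open.

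Lgr5-GFP cells of unlabelled stage correlated at 0.14 with E17.5 EpCAM epithelium, -0.021 with adult Lgr5-GFP cells, -0.059 with enteroids and -0.047 with E15.5 EpCAM epithelium; at equal length these values were 0.186, 0.027, -0.002 and -0.002. Chromosome Y held 0.359% of peaks in enteroids and 0.205% in adult Lgr5-GFP cells (43 to 221 peaks), and 0.059% to 0.143% in the other groups. Of 32 libraries, 20 had peaks both at 1 or more of 4 Y-linked genes and at Xist, 6 at Y-linked genes only, 3 at Xist only and 3 at neither. The 6 with Y-linked peaks only and the 3 with neither were all Bmi1-GFP libraries. Every EpCAM and Lgr5-GFP library had a peak at Xist. Bmi1-GFP lists were also short, so sex, list length and reporter cannot be told apart here. Regions on chromosome X entered the comparisons.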
